A study of Mus musculus with 18 samples.

How the data were processed

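The deposited files are 3 tables of counts per Ensembl gene, 1 per set of 6 libraries, with 1 column per library, and the values in them are whole numbers. Per the labels, total RNA was taken with Trizol, libraries were made with a standard Illumina protocol, and the authors aligned the reads with HISAT2 2.1.0 to GRCm38. The counting tool, the annotation release and the strandedness are not given in the sources used here. The tables listed 52550, 53465 and 53465 genes, 52506 of them in all 3, and symbols and coordinates came from GENCODE M21, which held 99.7%, 99.6% and 99.6% of the IDs. Total counts per library ran from 20156082 to 24331577.

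Groups and set membership were taken from the sample labels, with 3 libraries in each of 6 groups. Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr by group, robust quasi-likelihood F test, two-sided, Benjamini-Hochberg adjustment over the genes tested, threshold 0.05). Each ligand was compared with the libraries without ligand of its own set, in a fit of those 6 libraries. In set 3 those libraries held the inhibitor. Differences between effects were tested as contrasts of 4 group means in a fit of 12 libraries, as were R against DNT and RA against ADO, and DNT against WT was fitted on 6. Each fit gave a gene a single dispersion over all its libraries, also where the sets differed in spread. The SE of a log2 fold change is its size divided by the square root of F. The CPM values given for genes were scaled with the TMM factors. Principal components used log2 CPM with a prior count of 3.

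The 33 gene lists, the tests, the alternatives, a panel of 12 genes and the rule for naming genes were fixed before the data were examined. For each treatment comparison the rule named the 6 largest rises and the 6 largest falls among genes with adjusted p under 0.05, a mean of at least 5 CPM in a group, every treated library on the same side of every control library, and a symbol that is not a model name or a receptor segment. For each list it named the 4 members with the smallest p, and for each difference test the 5 largest in either direction together with the genes named for the treatments. Other members given as examples in the difference tests were chosen after their values were seen. Lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM with a preset correlation of 0.01, adjusted over the lists of a comparison, beside counts of members past the threshold over all genes and adjusted over the list alone. Camera with an estimated correlation and fry, which tests whether a list moves at all, were alternatives. Per-library list values are medians over members of log2 CPM with an offset of 0.5, relative to the control mean of the set.

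Alternatives were DESeq2 1.42.0, RLE factors, library size only, no filter on low counts, at least 1 CPM in at least 3 libraries, all 18 libraries in a single fit, a block for replicate number, limma-voom, a test against a log2 fold change of 0.5 (glmTreat), and leaving out each library in turn. An offset over transcript length and weights per set were added after the data were seen. The tests were tested on simulated data with the size, dispersions and depth of each comparison, in 5 data sets with 200 changed genes each. There each gene had the same dispersion in all libraries of a comparison, whereas in the real data R varied far more than RA. Most real comparisons also called more genes than were changed there. The rates that follow may therefore not hold where the spread is unequal. With per-gene dispersions edgeR recovered 70.1%, 84.8% and 51.9% of 2-fold changes in the ATPgs, adenosine and inhibitor comparisons, and 37.6% and 59.7% in the differences with and without inhibitor and between ligands. False calls were 9.33%, 6.47%, 6.74%, 5.81% and 5.39% of calls. Camera found a shifted list of 30 genes in 5 of 5 data sets in each. The simulated genes were drawn independently, so this cannot judge the preset correlation. Python 3.11.15 with matplotlib 3.10.9 drew the figures. No library was left out, and sequence reads were not used here.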

Results

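RNA was sequenced from 18 libraries of mouse double negative T cells (DNT cells), which lack CD4 and CD8 and were here made by conversion of CD4+ T cells from wild type spleen and lymph node. All had been stimulated through CD3 and CD28. The study asks what purinergic signalling, that is, signalling by extracellular ATP and adenosine, does in these cells. The libraries formed 3 sets of 6, each a separate table of counts, and each set held 3 libraries without and 3 with an added ligand for 6 h. Set 1 compared no ligand (WT) with 400 µM ATPgs (WTATPgs), an ATP analogue described as non-hydrolysable. Set 2 compared no ligand (DNT) with 400 µM adenosine (ADO). Set 3 made the adenosine comparison in the presence of 250 nM of an inhibitor of the adenosine A2a receptor (A2aR), without adenosine (R) and with it (RA).

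Total counts per library were 22112929, 22126825 and 22987327 in WT, and 22644135, 22482700 and 24331577 in WTATPgs. In set 2 they were 23855783, 21967706 and 22758766 in DNT, and 22280641, 22428095 and 22319036 in ADO. In set 3 they were 20156082, 22914344 and 20737964 in R, and 20500188, 22176531 and 21781073 in RA. Nothing in the labels says that the 3 libraries of a group came from separate cultures or animals, so the p-values measure only the spread between these libraries. The main axis of variation held 65.4% of the variance and parted set 3 from the other sets. Set 3 also had larger shares of ribosomal protein RNA (10.9% to 16.9% of counts in R) and of mitochondrially encoded RNA (3.14% to 5.47% in R) than the untreated libraries of set 2, where the means were 5.52% and 1.68%. The common biological coefficient of variation was 10.6% in set 1, 2.74% in set 2 and 19.6% in set 3. Gzmb, which encodes the killer protease granzyme B, had a mean of 14302 CPM in WT (SD 258, n = 3). In contrast, Cd4 had 9.33 CPM there (SD 1.38, n = 3). CPM is the count scaled to the total of its library after adjustment by the TMM factor.

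**Figure D1:**
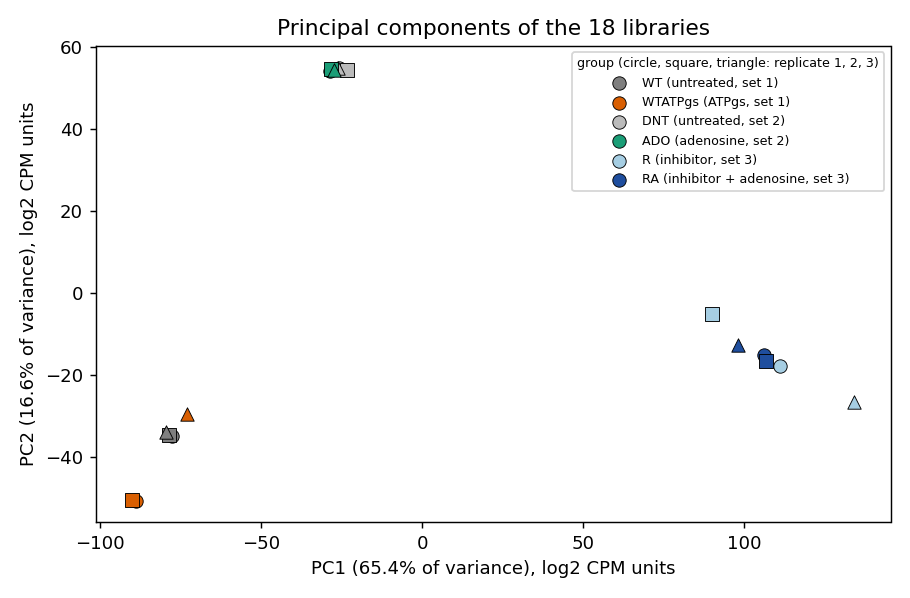
The first component (65.4% of variance, x axis) and the second (16.6%, y axis) of log2 CPM for the 18 libraries, each point 1 library, coloured by group. Set 3 lies apart from sets 1 and 2 on the first component.

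ATPgs against no ligand asked what an ATP-type signal changes in these cells. Il2, the gene of the T cell growth factor interleukin 2, fell by 2.73 ± 0.04 on the log2 scale (SE, n = 3 libraries per group, as for all fold changes), from 368 to 55.6 CPM (SD 8.49 and 0.447). Ifng, which encodes interferon gamma, fell by 1.34 ± 0.14, and Il10, which encodes an anti-inflammatory cytokine, fell by 1.05 ± 0.15. Crem, a transcription factor gene induced by cyclic AMP (cAMP), rose by 1.53 ± 0.04 (adjusted p = 9.07e-08), from 118 to 341 CPM (SD 2.32 and 6.16). The immediate early gene Fos rose by 2.17 ± 0.28. Of the genes that make or sense adenosine, Entpd1 (CD39, which degrades ATP) rose by 0.30 ± 0.06 and Nt5e (CD73, which makes adenosine) rose by 0.77 ± 0.14. Of the receptors, Adora2a (A2aR) fell by 0.27 ± 0.05 and Adora2b (0.08 ± 0.06, adjusted p = 0.317) did not pass. The killing genes Gzmb (−0.34 ± 0.03), Prf1 (perforin, −0.30 ± 0.05) and Fasl (Fas ligand, −0.24 ± 0.06) fell. Nr4a1, a gene induced by T cell receptor signals, rose by 0.56 ± 0.14 (adjusted p = 0.0309).

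In all, 2678 genes rose and 2934 fell of 15124 tested with ATPgs, of which 592 rose and 241 fell at least 2-fold. The balance turned to 3226 and 2331 when scaled to library size only, and to 3060 and 2642 with the transcript length offset. The largest rises among the genes that met the naming rule were Cd14 (4.25 ± 0.82), a myeloid receptor of bacterial lipopolysaccharide, Thbs1 (thrombospondin 1, 4.08 ± 0.77) and the mucin gene Muc3 (4.06 ± 0.66). Next came the myeloid lectin gene Clec4d (3.68 ± 0.85), Sgip1 (3.35 ± 0.21), which encodes an endocytic adaptor, and Il1f9 (interleukin 36 gamma, 3.32 ± 0.80). The largest falls were Adad1 (−3.35 ± 0.13), the chemokine gene Ccl1 (−2.99 ± 0.19), the synaptic scaffold gene Shank1 (−2.93 ± 0.22), Dmkn (−2.89 ± 0.33), Il2, and the growth factor gene Igf2 (−2.55 ± 0.12). Adad1 (chromosome 3, 37063527 to 37121930 in GRCm38) overlaps the end of Il2 (ENSMUSG00000027720, chromosome 3, 37120523 to 37125959) on the opposite strand, so its counts are uncertain. Crem (ENSMUSG00000063889) lies on chromosome 18 from 3266048 to 3337748, Ifng (ENSMUSG00000055170) on chromosome 10 from 118441046 to 118445892, and Entpd1 (ENSMUSG00000048120) on chromosome 19 from 40612366 to 40741602.

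Of 33 gene lists written before the data were examined, 18 are described here for each treatment and were picked after the results were seen. For the 2 difference tests those of the 18 that passed are described. Of 29 measured members of the cAMP-CREB list, which holds targets of cAMP signalling, 21 rose and 1 fell with ATPgs (21 and 1 adjusted over the list alone), among them Crem, the phosphodiesterase gene Pde4b (1.23 ± 0.05), Rgs2 (1.88 ± 0.07) and Areg (1.56 ± 0.08). The list test gave adjusted p = 4.38e-08, and adjusted p = 0.656 with an estimated correlation. Of 30 T cell cytokine genes 4 rose and 10 fell (4 and 10 adjusted over the list alone), among the falls Il2, Tnfsf8 (−1.32 ± 0.03), Tnfsf14 (−0.93 ± 0.03) and Tnf (−0.75 ± 0.04). The cytokine list had adjusted p = 0.00937, and adjusted p = 0.656 with an estimated correlation. Of 24 cholesterol synthesis genes 15 rose and 0 fell (16 and 0 adjusted over the list alone), among them Mvd (0.72 ± 0.06), Acat2 (0.90 ± 0.11), Hmgcs1 (0.52 ± 0.06) and Msmo1 (0.50 ± 0.06). The cholesterol list had adjusted p = 5.52e-05, and adjusted p = 0.656 with an estimated correlation. Of 22 T cell identity genes 1 rose and 9 fell (1 and 9 adjusted over the list alone). Il7r, the interleukin 7 receptor gene, rose by 1.18 ± 0.04, while Lat (−0.55 ± 0.04), Ptprc (−0.28 ± 0.03) and Cd4 (−2.13 ± 0.26) fell. The T cell identity list had adjusted p = 0.0103, and adjusted p = 0.656 with an estimated correlation. Another 2 lists served as signs of RNA quality. Of 40 ribosomal protein genes 0 rose and 30 fell with ATPgs (0 and 33 adjusted over the list alone), with adjusted p = 3.09e-08, the smallest of all lists tested with ATPgs, and adjusted p = 0.656 with an estimated correlation. Of 12 mitochondrially encoded genes 7 rose and 0 fell (8 and 0 adjusted over the list alone), with adjusted p = 0.00188, and adjusted p = 0.656 with an estimated correlation. Whether RNA quality took part in the other list changes was not tested.

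Of 30 activation and costimulation genes 6 rose and 15 fell with ATPgs (7 and 15 adjusted over the list alone, list test adjusted p = 0.0749), of which Icos (1.5 ± 0.04) went up and Egr2 (−1.14 ± 0.04), Irf4 (−0.74 ± 0.03) and Cd69 (−0.49 ± 0.04) down. Of 28 coinhibitory receptor genes 5 rose and 8 fell (7 and 9 adjusted over the list alone), Ikzf2 (1.05 ± 0.04) and Ctla4 (1.11 ± 0.05) upward, Lag3 (−0.90 ± 0.04) and Cd160 (−0.88 ± 0.05) downward. Of 28 chemokine genes 11 rose and 7 fell (12 and 7 adjusted over the list alone), Ccl3 (−1.16 ± 0.06), Ccl4 (−1.46 ± 0.08) and Ccl5 (−0.61 ± 0.05) downward and Cxcr4 (1.20 ± 0.11) upward. Of 27 cytotoxic effector genes 7 rose and 12 fell (8 and 12 adjusted over the list alone), with Serpinb6b (−0.67 ± 0.04), Tnfsf10 (−1.12 ± 0.07), Ctsw (−0.56 ± 0.04) and Gzmb among the falls. The cytotoxic list median of −0.02 turned positive when scaled to library size only or with a transcript length offset. Counts of rises and falls were 5 and 8 of 25 purinergic genes (5 and 8 adjusted over the list alone), 7 and 3 of 17 AP-1 genes (8 and 3) and 7 and 6 of 35 interferon response genes (7 and 6). They were 10 and 7 of 31 pro-apoptotic genes (10 and 7 adjusted over the list alone), 5 and 7 of 19 anti-apoptotic genes (6 and 7) and 8 and 12 of 33 amino acid stress genes regulated by ATF4 (10 and 13). Of 23 endoplasmic reticulum stress genes 3 rose and 11 fell (3 and 12 adjusted over the list alone). The endoplasmic reticulum stress list had adjusted p = 0.0205, and adjusted p = 0.753 with an estimated correlation. Of 40 cell cycle genes 12 rose and 1 fell (12 and 1 adjusted over the list alone). The cell cycle list had adjusted p = 0.026, and adjusted p = 0.754 with an estimated correlation. Median, mean and test did not share a sign for the cytotoxic, coinhibitory, anti-apoptotic and ATF4 lists with ATPgs, and for the chemokine list the test pointed up and fry down.

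Markers of other cells were measured beside these genes. Of 23 macrophage, monocyte and neutrophil genes 6 rose and 0 fell with ATPgs (3 and 0 adjusted over the list alone), among them Cd68 (0.93 ± 0.12), Cd14, Mpo (1.35 ± 0.34) and Fcgr1 (1.09 ± 0.33). The macrophage list had adjusted p = 0.00273, and adjusted p = 0.754 with an estimated correlation. The list median per library was 1.46, 1.54 and −0.14 in WTATPgs replicates 1 to 3. Of 18 B cell genes only Cd79b rose (0.90 ± 0.24; 0 adjusted over the list alone), and Cd79a (1.46 ± 0.49), H2-Ab1 (0.46 ± 0.17) and Ebf1 (0.95 ± 0.41) did not pass. Cd14 went from 0.967 CPM (SD 0.199) to 18.6 CPM (SD 11.8).

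**Figure D2:**
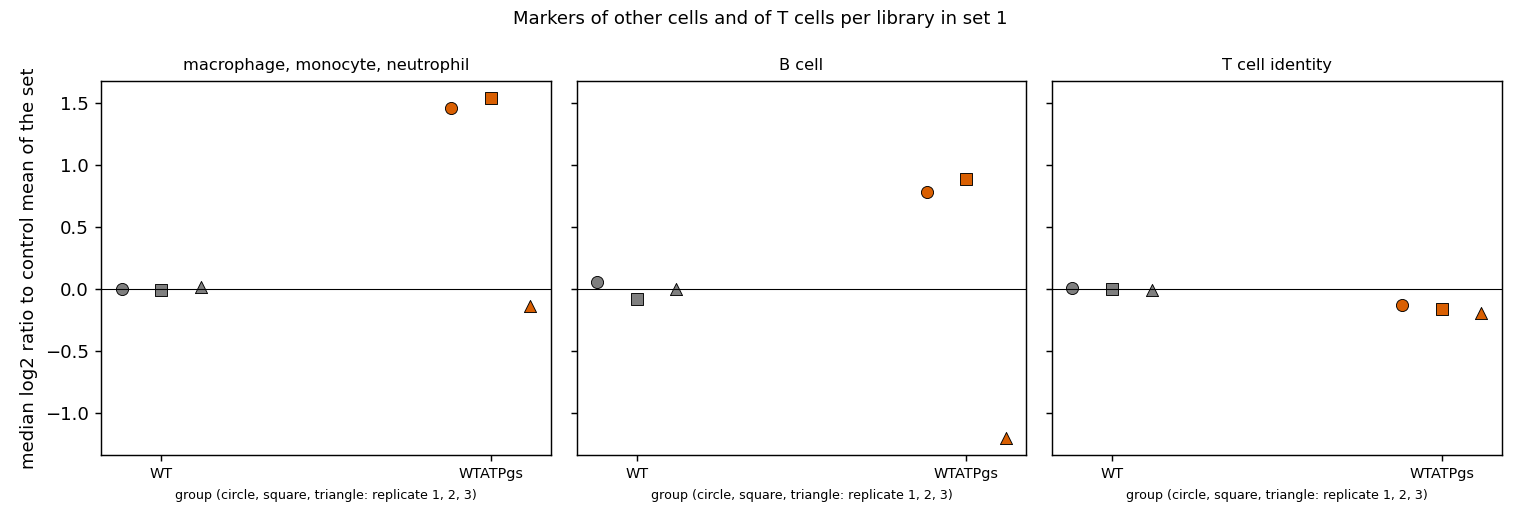
Median log2 ratio of marker lists (y axis) in each library of set 1 relative to the mean of the untreated libraries, for macrophage, B cell and T cell identity genes, each point 1 library. The macrophage list stood at 1.46, 1.54 and −0.14 in WTATPgs replicates 1 to 3.

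WTATPgs replicate 3 stood apart from the other ATPgs libraries, and without it 8381 genes passed (4186 higher, 4195 lower). Without WT replicate 1, 2 or 3, 1784, 1892 or 1778 rose. Without 1 of the WT libraries Cd14, Thbs1, Clec4d, Il1f9 and Nr4a1 no longer passed. Adjusted p over the alternatives ran from 2.55e-34 to 0.18 for Cd14 and 9.43e-37 to 0.0843 for Nr4a1. With limma-voom Cd14, Thbs1, Clec4d and Il1f9 did not pass (up to 0.18, 0.114, 0.194 and 0.187 over the alternatives). Nor did Thbs1 and Nr4a1 without WTATPgs replicate 1 or 2, Clec4d without replicate 1 or Il1f9 without replicate 2. Fasl was lost without WT replicate 1 or 3 or with the transcript length offset (adjusted p over the alternatives 6.62e-05 to 0.39). Without WTATPgs replicate 3 the cytokine and cell cycle lists had adjusted p = 0.0586 and 0.567, ranges over the alternatives 0.000668 to 0.656 and 0.00265 to 0.754. The B cell list then had adjusted p = 1.90e-05 (over the alternatives 1.90e-05 to 0.993). The endoplasmic reticulum stress list lost its call without WTATPgs replicate 1 or 2 (adjusted p = 0.083 and 0.0564, over the alternatives 4.07e-05 to 0.753). The activation list passed without WT replicate 2 or any 1 WTATPgs library and the AP-1 list without WTATPgs replicate 3 (adjusted p over the alternatives 0.015 to 0.656 and 0.0141 to 0.753). With all 18 libraries fitted together Gzmb and Prf1 no longer passed (adjusted p over the alternatives 7.61e-29 to 0.186 and 4.1e-25 to 0.0697).

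Adenosine against no ligand asked what the nucleoside itself changes. Il2 fell by 2.87 ± 0.06 (adjusted p = 2.31e-37), from 62.5 to 8.54 CPM (SD 0.557 and 0.952), and Il10 fell by 2.07 ± 0.08. Ifng fell by 1.32 ± 0.02, from 1506 to 601 CPM (SD 23.6 and 24.3). Crem rose by 1.24 ± 0.03, Fos by 0.97 ± 0.09 and Nr4a1 by 0.51 ± 0.02. Nt5e rose by 0.88 ± 0.04 and Adora2a by 0.12 ± 0.03, while Entpd1 (−0.41 ± 0.04) and Adora2b (−0.16 ± 0.05, adjusted p = 0.00848) fell. Gzmb (−0.19 ± 0.01) and Prf1 (−0.47 ± 0.02) fell, and Fasl (0.03 ± 0.04, adjusted p = 0.513) did not pass.

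With adenosine 3707 genes rose and 3574 fell of 14512 tested, of which 364 rose and 243 fell at least 2-fold. Scaled to library size only, 4418 rose and 2850 fell. The largest named rises were Sgip1 (5.28 ± 0.25, from 0.196 to 7.69 CPM), the insulin-like growth factor receptor gene Igf1r (3.62 ± 0.08), and Ramp3 (2.78 ± 0.05), whose product pairs with the calcitonin receptor-like receptor. Next came Ifit1bl1 (2.74 ± 0.13), the urokinase receptor gene Plaur (2.66 ± 0.10) and the repressor gene Scrt1 (2.43 ± 0.19). The largest named falls were Il2, Ccl1 (−2.70 ± 0.03), the growth factor gene Fgf18 (−2.25 ± 0.19), the lipase gene Mgll (−2.18 ± 0.11), Il10 and the lymphotoxin gene Lta (−2.04 ± 0.04). Ifit1bl1 belongs to a family of near-identical genes, so its counts are uncertain. Sgip1 (ENSMUSG00000028524) lies on chromosome 4 from 102741297 to 102973628, Ramp3 (ENSMUSG00000041046) on chromosome 11 from 6658521 to 6677475, and Il10 (ENSMUSG00000016529) on chromosome 1 from 131019845 to 131024974.

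**Figure D3:**
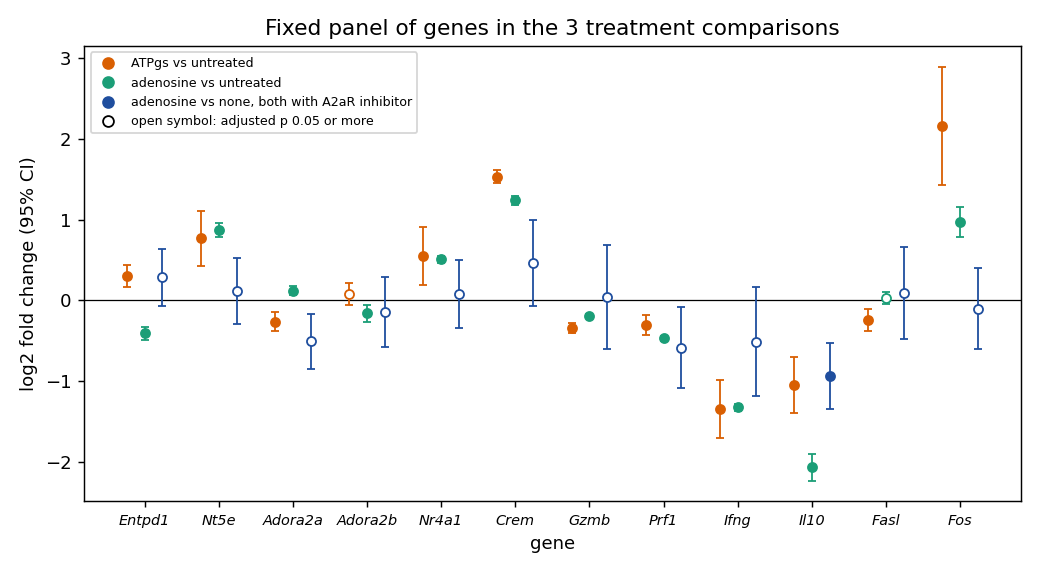
Log2 fold changes (y axis) of 12 genes fixed beforehand in the 3 treatment comparisons, with 95% confidence intervals, n = 3 libraries per group, where open symbols have adjusted p of at least 0.05. Crem stood at 1.53 with ATPgs, 1.24 with adenosine and 0.46 with adenosine under the inhibitor, the last not past the threshold.

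Of 36 interferon response genes, which respond to interferons and viral RNA, 31 rose and 1 fell with adenosine (31 and 1 adjusted over the list alone), among them Gbp2 (1.32 ± 0.03), Zbp1 (0.91 ± 0.03), Ifi47 (0.86 ± 0.03) and Iigp1 (0.93 ± 0.03). The interferon list had adjusted p = 4.38e-18, and adjusted p = 0.0244 with an estimated correlation. Of 40 cell cycle genes 34 rose and 0 fell (36 and 0 adjusted over the list alone), among them Cenpa (1.04 ± 0.03), Rrm2 (0.48 ± 0.03), Mki67 (0.40 ± 0.03) and Mcm7 (0.43 ± 0.03). The cell cycle list had adjusted p = 1.42e-13, and adjusted p = 0.0244 with an estimated correlation. Of 31 T cell cytokine genes 5 rose and 21 fell (5 and 21 adjusted over the list alone), the falls including Csf2 (−1.77 ± 0.03), Lta, Tnf (−1.12 ± 0.02) and Il2. The cytokine list had adjusted p = 1.02e-07, and adjusted p = 0.0245 with an estimated correlation. Of 33 ATF4-type amino acid stress genes 2 rose and 27 fell (2 and 27 adjusted over the list alone), with Slc7a5 (−0.53 ± 0.02), Slc1a5 (−0.29 ± 0.02) and Sars (−0.30 ± 0.02) down and Ddit4 (0.50 ± 0.03) up. The ATF4 list had adjusted p = 8.82e-11, and adjusted p = 0.0244 with an estimated correlation. Of 23 endoplasmic reticulum stress genes 2 rose and 20 fell (2 and 20 adjusted over the list alone), with Hspa5 (−0.39 ± 0.01), Pdia6 (−0.36 ± 0.02) and Hyou1 (−0.34 ± 0.02) down and Ern1 (0.60 ± 0.04) up. The endoplasmic reticulum stress list had adjusted p = 2.44e-08, and adjusted p = 0.0679 with an estimated correlation. Among the signs of RNA quality, 0 rose and 6 fell of 12 mitochondrially encoded genes (0 and 6 adjusted over the list alone), with adjusted p = 0.00882, and adjusted p = 0.612 with an estimated correlation. Of 40 ribosomal protein genes 3 rose and 15 fell (3 and 15 adjusted over the list alone, list adjusted p = 0.123).

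Of 30 activation genes 8 rose and 19 fell with adenosine (9 and 20 adjusted over the list alone), the falls including Irf4 (−0.93 ± 0.02), Egr2 (−1.03 ± 0.03), Myc (−0.55 ± 0.02) and Slc7a5. The activation list had adjusted p = 3.46e-05, and adjusted p = 0.391 with an estimated correlation. Of 29 cAMP-CREB genes 15 rose and 8 fell (15 and 9 adjusted over the list alone), with Crem, Rgs2 (1.62 ± 0.04) and the phosphodiesterase gene Pde4d (1.37 ± 0.05) up and Gem (−0.55 ± 0.02) down. The cAMP-CREB list had adjusted p = 0.0305, and adjusted p = 0.388 with an estimated correlation. Of 25 cholesterol synthesis genes 13 rose and 2 fell (13 and 2 adjusted over the list alone). The cholesterol list had adjusted p = 0.00898, and adjusted p = 0.533 with an estimated correlation. Of 27 cytotoxic effector genes 12 rose and 13 fell (12 and 13 adjusted over the list alone). The natural killer receptor gene Klrd1 rose by 1.21 ± 0.03, and Prf1, Tnfsf10 (−1.01 ± 0.04) and Gzmc (−0.33 ± 0.02) fell. Gzmc is 1 of several near-identical granzyme genes, so its counts are uncertain. The cytotoxic list median of −0.04 turned positive when scaled to library size only. Of 25 purinergic genes 7 rose and 9 fell (7 and 9 adjusted over the list alone), with the lysophospholipid receptor gene P2ry10 (1.28 ± 0.03), Nt5e and Dpp4 (0.56 ± 0.06) up and Entpd1 down.

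Counts of rises and falls with adenosine were 13 and 7 of 26 chemokine genes (13 and 7 adjusted over the list alone), 13 and 10 of 28 coinhibitory genes (13 and 11) and 5 and 9 of 16 AP-1 genes (5 and 10). They were 13 and 6 of 31 pro-apoptotic genes (13 and 6 adjusted over the list alone) and 7 and 7 of 19 anti-apoptotic genes (8 and 7). Among markers they were 12 and 7 of 22 T cell identity genes (12 and 7 adjusted over the list alone), 5 and 2 of 11 macrophage genes (6 and 2) and 3 and 2 of 8 B cell genes (3 and 2). None of these 8 lists passed the threshold. Median, mean and test did not share a sign for the purinergic, cytotoxic and anti-apoptotic lists. For chemokines the list test pointed up and fry, the self-contained test, down (adjusted p = 0.0266, range over the alternatives 0.0266 to 0.677). Adora2b no longer passed without DNT replicate 1 or ADO replicate 1, with DESeq2 or scaled to library size only (adjusted p over the alternatives 0.0016 to 0.403). With all 18 libraries fitted together 1439 genes rose and 870 fell, and Gzmb, Adora2a and Adora2b no longer passed (for the first 2 adjusted p over the alternatives 2.84e-65 to 0.574 and 6.05e-07 to 0.288).

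The same comparison under the A2aR inhibitor asked which adenosine effects remain in its presence. How fully the inhibitor blocked the receptor was not tested. Il2 fell by 2.70 ± 0.24 (adjusted p = 0.00124), from 66.6 to 10.2 CPM (SD 20.2 and 1.0), and Il10 by 0.93 ± 0.18 (adjusted p = 0.0445). Crem (0.46 ± 0.24, adjusted p = 0.489), Ifng (−0.52 ± 0.30, adjusted p = 0.568), Prf1 (−0.59 ± 0.22, adjusted p = 0.303) and Adora2a (−0.51 ± 0.15, adjusted p = 0.171) did not pass. Nor did Entpd1 (0.29 ± 0.16), Nt5e (0.12 ± 0.18), Adora2b (−0.14 ± 0.19), Nr4a1 (0.07 ± 0.19), Gzmb (0.04 ± 0.29), Fasl (0.10 ± 0.25) or Fos (−0.10 ± 0.22), with adjusted p from 0.525 to 0.977.

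Under the inhibitor 37 genes rose and 110 fell with adenosine of 12873 tested, of which 30 rose and 101 fell at least 2-fold. The largest named rises were Ramp3 (4.02 ± 0.24, from 1.22 to 20.1 CPM), Plaur (2.64 ± 0.25), the chemokine gene Cxcl3 (2.36 ± 0.19), Tg (thyroglobulin, 1.68 ± 0.25), the glutamate transporter gene Slc1a2 (1.59 ± 0.20) and Nebl (1.47 ± 0.21). The largest named falls were Rsad2 (−3.85 ± 0.27), which encodes the antiviral protein viperin, Fgf18 (−3.06 ± 0.22) and the signalling adaptor gene Sh2d1b2 (−2.75 ± 0.20). Next came the interferon-induced chaperone gene Rtp4 (−2.74 ± 0.27), Il2, and Ifi204 (−2.56 ± 0.24), which encodes a DNA sensor. Rsad2 went from 9.01 to 0.622 CPM (SD 1.95 and 0.0615). Rsad2 (ENSMUSG00000020641) lies on chromosome 12 from 26442746 to 26456452.

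Of 32 interferon response genes 0 rose and 13 fell under the inhibitor (0 and 17 adjusted over the list alone), among them Rsad2, Rtp4, the oligoadenylate synthetase-like gene Oasl1 (−3.33 ± 0.33) and Irf7 (−1.93 ± 0.19), the interferon regulator. The interferon list had adjusted p = 6.46e-19, and adjusted p = 0.106 with an estimated correlation. Of 40 cell cycle genes only Cdc6 rose (0.88 ± 0.16; 1 adjusted over the list alone), while Cenpf (0.67 ± 0.19), Cdk2 (0.66 ± 0.20) and Cdc45 (0.50 ± 0.16) did not pass. The cell cycle list had a median of 0.38, adjusted p = 8.86e-11, and adjusted p = 0.0444 with an estimated correlation. Of 29 T cell cytokine genes 1 rose and 7 fell (4 and 12 adjusted over the list alone), with Il2, Lta (−1.61 ± 0.16) and Il6 (−1.22 ± 0.17) down and Il17f (1.15 ± 0.16) up. The cytokine list had adjusted p = 0.0197, and adjusted p = 0.305 with an estimated correlation. The cytokine list median of −0.14 turned positive when scaled to library size only, a setting that shifted the median of all genes by 0.117. Of 9 macrophage genes 0 rose and 2 fell (0 and 3 adjusted over the list alone), the Fc receptor gene Fcgr3 (−1.61 ± 0.17) and Tyrobp (−1.63 ± 0.18). In contrast, Fcer1g (−0.71 ± 0.18) and Mpeg1 (−0.94 ± 0.43) did not pass. The macrophage list had adjusted p = 0.0272, and adjusted p = 0.305 with an estimated correlation. Of 7 B cell genes 0 passed (0 and 2 adjusted over the list alone, list adjusted p = 0.0189, and adjusted p = 0.305 with an estimated correlation). Of 30 activation genes 0 rose and 1, Nfkbid (−0.87 ± 0.16), fell (2 and 4 adjusted over the list alone), while Icos, Cd40lg and Myc did not pass. The activation list had adjusted p = 0.0125, and adjusted p = 0.513 with an estimated correlation. Of the signs of RNA quality, 0 of 40 ribosomal protein genes passed and their list pointed down with adjusted p = 0.0125, and adjusted p = 0.853 with an estimated correlation. None of 13 mitochondrially encoded genes passed (list adjusted p = 0.393).

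**Figure D4:**
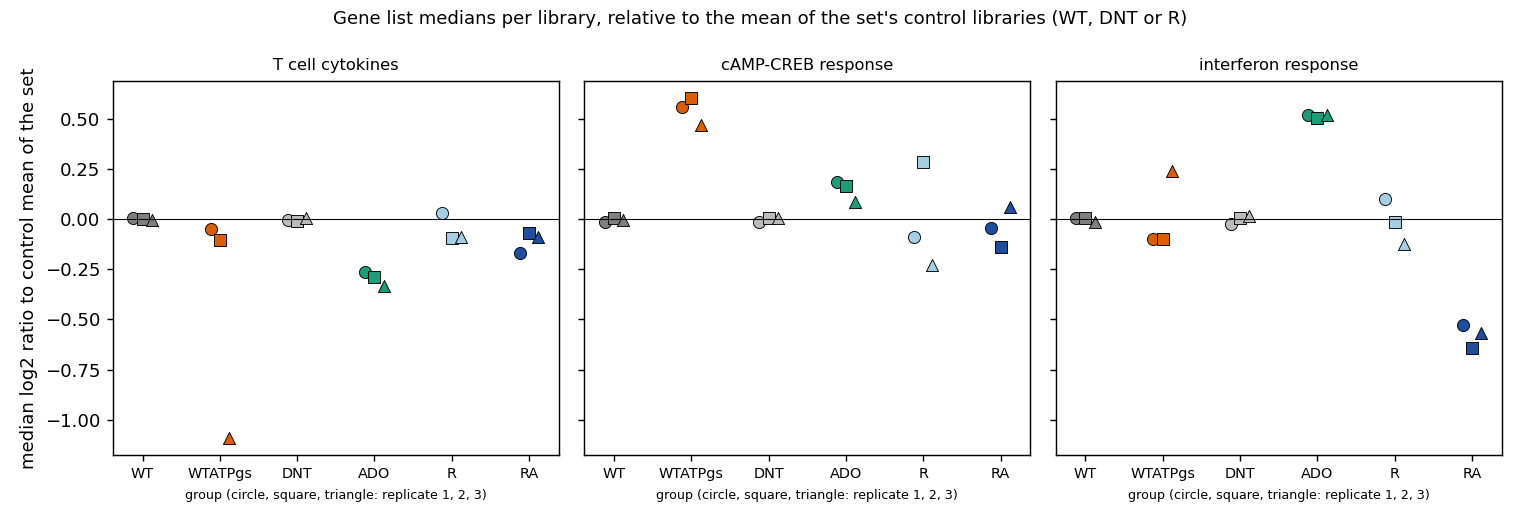
Median log2 ratio per library (y axis, relative to the mean of the untreated or inhibitor-only libraries of the same set) for T cell cytokine, cAMP-CREB and interferon response genes, each point 1 library. The interferon list stood at 0.52, 0.51 and 0.52 in the ADO libraries and, by fold change, at −0.60 with adenosine under the inhibitor (the cytokine and cAMP-CREB medians there change sign when scaled to library size only).

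For the other lists under the inhibitor, rises and falls were 0 and 1 of 29 cAMP-CREB genes (1 and 3 adjusted over the list alone, list test adjusted p = 0.748), the fall being Atf3 (−1.02 ± 0.17) while Pde4b, Nr4a2 and Gem did not pass. They were 0 and 1 of 16 AP-1 genes (0 and 2 adjusted over the list alone) and 0 and 1 of 27 cytotoxic genes (0 and 2). They were 3 and 2 of 25 chemokine genes (5 and 5 adjusted over the list alone), 1 and 1 of 27 coinhibitory genes (4 and 4), 1 and 0 of 31 pro-apoptotic genes (1 and 1), and 1 and 0 of 22 T cell identity genes (1 and 1). None passed of 22 purinergic genes (0 and 1 adjusted over the list alone), 19 anti-apoptotic (0 and 1), 33 ATF4 (0 and 0), 23 endoplasmic reticulum stress (0 and 0) or 24 cholesterol synthesis genes (0 and 0). Scaling to library size only turned the medians of the purinergic, cAMP-CREB, cytotoxic, coinhibitory, both apoptosis, T cell identity and macrophage lists from negative to positive. The test pointed up and the median down for the coinhibitory and pro-apoptotic lists. Without R replicate 3 the count was 1719 (725 higher, 994 lower). It was 48 and 220 without R replicates 1 and 2 and 36, 45 and 38 without RA replicates 1, 2 and 3. Il10 no longer passed without R replicate 1 or any RA library, with RLE factors, with library size only or with a replicate block (adjusted p over the alternatives 0.000103 to 0.31). Without R replicate 1 or any RA library Tg and Nebl did not pass either (1.73e-08 to 0.0883 and 2.28e-06 to 0.0875), and without RA replicate 1 Slc1a2 did not (8.07e-09 to 0.0565). Without R replicate 3 Crem rose by 0.79 (adjusted p = 0.00146, over the alternatives 0.00146 to 0.905), and Prf1, Adora2a and Fasl also passed. The macrophage list lost its call without R replicate 1 or 3 or RA replicate 3 (adjusted p = 0.0828, 0.0957 and 0.0604, over the alternatives 0.00722 to 0.305). The cytokine and B cell lists lost theirs without R replicate 1 (adjusted p = 0.0891 and 0.0937, over the alternatives 0.00822 to 0.305 and 0.00722 to 0.305). The AP-1, ATF4 and cholesterol lists passed without R replicate 3 and the cytotoxic and endoplasmic reticulum stress lists without R replicate 2 (lowest adjusted p over the alternatives 0.023, 0.0139, 0.00976, 0.00735 and 0.024).

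The test of the adenosine effect with minus without the inhibitor asked which effects differed in the presence of the inhibitor. It compares set 3 with set 2, so the inhibitor and the set cannot be told apart. The fit of both sets gave each gene 1 dispersion. The common coefficient of variation was 2.74% in set 2 and 19.6% in set 3. The SEs and adjusted p-values of the difference may therefore be too small. The difference was positive for 136 genes and negative for 469 of 14918 tested. The most negative were the interferon-induced genes Ifit1bl1 (−5.36 ± 0.66), Rsad2 (−4.66 ± 0.20, adjusted p = 1.21e-07), Oasl1 (−3.69 ± 0.27), Ifit3 (−3.65 ± 0.38) and Rtp4 (−3.64 ± 0.25). The most positive were the dynein gene Dnah17 (2.13 ± 0.47), Cyp1b1 (1.85 ± 0.32), the retinol transporter gene Stra6 (1.72 ± 0.21), the amino acid transporter gene Slc7a2 (1.69 ± 0.22) and Cxcl3 (1.39 ± 0.15). Ifit1bl1 had few counts in set 3, so its difference is imprecise, and Ifit1bl1 and Ifit3 have near-identical relatives. Oasl1 (ENSMUSG00000041827) lies on chromosome 5 from 114923240 to 114937915. The difference passed for Il10 (1.11 ± 0.20), Entpd1 (0.68 ± 0.13), Fos (−1.08 ± 0.20), Adora2a (−0.65 ± 0.13) and Nt5e (−0.78 ± 0.18). It did not pass for Crem (−0.81 ± 0.29, adjusted p = 0.151), Ifng (0.77 ± 0.36), Nr4a1 (−0.45), Adora2b (0.00), Gzmb (0.20), Prf1 (−0.13), Fasl (0.03) or Il2 (0.14, 95% confidence interval −0.48 to 0.76). Of the other genes named with adenosine, it passed for Ccl1 (1.21), Ramp3 (1.22), Igf1r (−1.23), Ifi204 (−3.22), Sh2d1b2 (−2.70) and Slc1a2 (1.19), and not for Tg (0.17), Nebl (0.14), Lta (0.42), Fgf18 (−0.83), Mgll (0.49), Plaur (−0.03), Sgip1 (−1.53) or Scrt1 (−1.16).

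The interferon response list held 0 positive and 26 negative differences of 36 genes (0 and 33 adjusted over the list alone), among them Irf7 (−2.83) and Usp18 (−2.07). The interferon list had adjusted p = 4.67e-43, and adjusted p = 6.55e-05 with an estimated correlation. Endoplasmic reticulum stress genes held 3 positive and 0 negative of 23 (4 and 0 adjusted over the list alone), Creld2 (0.73), Sdf2l1 (0.54) and Dnajc3 (0.53). The endoplasmic reticulum stress list had adjusted p = 4.24e-07, and adjusted p = 0.00451 with an estimated correlation. These 2 lists kept their call with an estimated correlation, and the following 6 did not. The cAMP-CREB list held 0 positive and 2 negative of 29 (0 and 6 adjusted over the list alone), the phosphatase gene Dusp1 (−1.15) and Rgs2 (−1.82). The cAMP-CREB list had adjusted p = 0.00452, and adjusted p = 0.385 with an estimated correlation. The cytokine list held 6 positive and 3 negative of 31 (7 and 5 adjusted over the list alone), among them Il17f (1.28) and Ltb (−0.88). The cytokine list had adjusted p = 0.0409, and adjusted p = 0.133 with an estimated correlation. Differences passed in 0 and 0 of 33 ATF4 genes (adjusted p = 0.00452, and adjusted p = 0.203 with an estimated correlation). They passed in 0 and 3 of 25 cholesterol genes (0 and 8 adjusted over the list alone, adjusted p = 4.36e-05, and adjusted p = 0.0716 with an estimated correlation). Among markers they passed in 0 and 3 of 12 macrophage genes (0 and 5 adjusted over the list alone, adjusted p = 0.000137, and adjusted p = 0.0716 with an estimated correlation) and 0 and 1 of 8 B cell genes (0 and 4, adjusted p = 0.00871, and adjusted p = 0.150 with an estimated correlation).

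Without R replicate 3 the counts of this difference were 1633 and 1417, without R replicate 2 they were 760 and 722. Without any 1 library of DNT or ADO the total was 280 to 317, and without RA replicates 1, 2 or 3 it was 372, 331 or 332. The call of Nt5e ended without any 1 library of DNT, ADO or RA and that of Dnah17 without 7 of the 12 libraries (adjusted p over the alternatives 0.00202 to 0.157 and 0.00167 to 0.273). That of Adora2a ended without DNT replicate 1 (adjusted p over the alternatives 2.28e-08 to 0.192). Scaled to library size only, Entpd1, Fos and Adora2a did not pass (up to 0.0869, 0.118 and 0.192 over the alternatives), and with a replicate block these, Nt5e, Il10 and Cyp1b1 did not. The call of Cyp1b1 ended also with all 18 libraries fitted together (adjusted p over the alternatives 0.000149 to 0.235), and those of Cyp1b1, Dnah17 and Fos with weights per set. Without R replicate 3 the differences for Ifng (1.30), Crem (−0.40), Gzmb (0.57), Fasl (0.50) and Nr4a1 (−0.51) passed. Crem and Nr4a1 then had adjusted p = 0.0201 and 0.0128 (over the alternatives 0.00959 to 0.284 and 0.0128 to 0.6). The cAMP-CREB list lost its call without R replicate 2 (adjusted p = 0.0893, over the alternatives 0.000263 to 0.385). The B cell list lost its call without R replicate 1 (adjusted p = 0.0823, over the alternatives 0.0065 to 0.15). The cytokine list lost it without R replicate 2 or 3, RA replicate 1 or 2 or ADO replicate 3 (0.0503 to 0.122, over 0.00279 to 0.133).

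The ATPgs effect minus the adenosine effect asked where the ligands differ. ATPgs carries a chain of phosphates on its ribose that adenosine lacks, both were given at 400 µM for 6 h, and each was tested in a set of its own, so ligand and set cannot be told apart. The fit of both sets again gave each gene 1 dispersion. The common coefficient of variation was 10.6% in set 1 and 2.74% in set 2. Its SEs may therefore be too small for the set 1 part. The difference was positive for 1284 genes and negative for 1440 of 15788 tested, and for 1434 and 1266 with the transcript length offset. The most positive were the complement receptor gene C5ar1 (2.14 ± 0.47), the heat shock gene Hspa1a (2.13 ± 0.29), A3galt2 (2.11 ± 0.42), the zinc finger gene Plagl1 (2.0 ± 0.43) and the phosphatase gene Dusp8 (1.91 ± 0.32). The most negative were Art2b (−2.09 ± 0.18), which encodes a surface ADP-ribosyltransferase, the receptor gene Slamf6 (−2.07 ± 0.21), Sgip1 (−1.92 ± 0.42), Igf1r (−1.89 ± 0.11, adjusted p = 2.94e-08) and the folate carrier gene Slc25a32 (−1.82 ± 0.27). Reads of Hspa1a and its near-identical neighbour Hspa1b cannot be assigned with certainty. Myeloid markers were higher only in WTATPgs replicates 1 and 2. Whether RNA of other cells took part in these differences, such as that of C5ar1, was not tested. The difference passed for Crem (0.30 ± 0.05), Fos (1.20 ± 0.33), Il10 (1.02 ± 0.17), Entpd1 (0.72 ± 0.07), Adora2a (−0.38 ± 0.05), Adora2b (0.25 ± 0.08), Gzmb (−0.15 ± 0.04), Fasl (−0.27 ± 0.07), Mgll (1.32) and Shank1 (−0.89). It did not pass for Il2 (0.15, 95% confidence interval −0.01 to 0.31), Ifng (−0.01 ± 0.17), Nr4a1 (0.05), Nt5e (−0.10), Prf1 (0.17 ± 0.07), Lta (0.56), Ccl1 (−0.29), Ramp3 (0.16) or Plaur (−0.01). Nor did it pass for the other genes named with either ligand, Cd14 (1.65 ± 1.27), Thbs1 (2.83 ± 1.09), Clec4d (3.12 ± 1.42), Muc3 (0.02 ± 1.36), Adad1 (−0.60), Dmkn (−0.38), Igf2 (−1.08), Ifit1bl1 (−1.67), Scrt1 (−0.03) and Fgf18 (−0.02). No difference is given for Il1f9, which was at 0 counts in all libraries of set 2.

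The cAMP-CREB list held 15 positive and 0 negative differences of 29 (17 and 0 adjusted over the list alone), among them Gem (0.51) and Nfil3 (0.65). The cAMP-CREB list had adjusted p = 6.75e-11, and adjusted p = 0.110 with an estimated correlation. AP-1 genes held 8 positive and 1 negative of 17 (9 and 1 adjusted over the list alone), among them Atf3 (1.0), Fosl2 (0.66), Batf3 (1.27) and Maff (1.29). The AP-1 list had adjusted p = 8.49e-06, and adjusted p = 0.110 with an estimated correlation. Interferon response genes held 1 positive and 16 negative of 36 (1 and 22 adjusted over the list alone), among them Ifit2 (−1.49), Mx1 (−0.83), Oas1a (−0.84) and Gbp2 (−1.48). The interferon list had adjusted p = 6.75e-11, and adjusted p = 0.139 with an estimated correlation. ATF4 genes held 19 positive and 2 negative of 33 (21 and 2 adjusted over the list alone), among them Trib3 (0.67), Slc3a2 (0.44), Slc1a4 (0.51) and Atf5 (0.72). The ATF4 list had adjusted p = 5.58e-09, and adjusted p = 0.110 with an estimated correlation. T cell identity genes held 1 and 7 of 22 (1 and 13 adjusted over the list alone, adjusted p = 5.23e-05, and adjusted p = 0.110 with an estimated correlation). Cell cycle genes held 0 and 14 of 40 (1 and 22 adjusted over the list alone, adjusted p = 4.76e-06, and adjusted p = 0.531 with an estimated correlation). Endoplasmic reticulum stress genes held 5 and 0 of 23 (5 and 0 adjusted over the list alone, adjusted p = 0.00373, and adjusted p = 0.531 with an estimated correlation). Cholesterol synthesis genes held 6 and 0 of 25 (6 and 0 adjusted over the list alone, adjusted p = 0.00373, and adjusted p = 0.531 with an estimated correlation). Macrophage genes held 3 and 0 of 23 (3 and 0 adjusted over the list alone, adjusted p = 0.00373, and adjusted p = 0.545 with an estimated correlation). The signs of RNA quality differed too. Mitochondrially encoded genes held 8 and 0 of 12 (9 and 0 adjusted over the list alone, adjusted p = 3.60e-09, and adjusted p = 0.110 with an estimated correlation). Ribosomal protein genes held 0 and 16 of 40 (0 and 22 adjusted over the list alone, adjusted p = 3.38e-08, and adjusted p = 0.531 with an estimated correlation).

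Without WTATPgs replicate 3 this difference was positive for 2309 genes and negative for 3058, and with all 18 libraries fitted together for 157 and 145. The calls of Adora2b and Fos ended without most single libraries (adjusted p over the alternatives 0.000249 to 0.573 and 6.52e-19 to 0.206). Without WTATPgs replicate 3 the differences for Nr4a1 (0.18), Ifng (−0.20) and Prf1 (0.09) passed, and the endoplasmic reticulum stress list lost its call (adjusted p = 0.415, over the alternatives 0.000234 to 0.531), while the B cell list passed (adjusted p = 0.000583, over the alternatives 0.000583 to 0.905). With all 18 libraries fitted together Crem, Gzmb, Fasl and Adora2a no longer passed (up to 0.71, 0.863, 0.721 and 0.0573), nor did Gzmb and Fasl with the transcript length offset. With limma-voom Plagl1 and Sgip1 did not pass (up to 0.132 and 0.087 over the alternatives), and Plagl1 did not with weights per set.

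Of 14053 genes tested with both ligands, 1615 rose with both (665 expected if the calls were independent), 1907 fell with both (726 expected) and 282 moved in opposite directions (1394 expected). Fold changes correlated across genes, which are not independent replicates, with Pearson's r 0.59 and Spearman's rho 0.55. Crem, Fos, Nt5e, Sgip1 and Ramp3 were among the genes higher with both, and Il2, Ifng, Il10, Prf1 and Ccl1 among those lower with both. Of 12484 genes tested for adenosine without and with the inhibitor, 33 rose in both (9.99 expected), 40 fell in both (27.9 expected) and 32 moved in opposite directions (38.5 expected), with r 0.36 and rho 0.29 across genes. Among calls of at least 2-fold, 16 rose in both (0.532 expected), 20 fell in both (0.989 expected) and 0 moved in opposite directions (2.04 expected). Ramp3 and Plaur rose in both and Il2, Lta, Ccl1 and Fgf18 fell in both.

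Comparisons between sets asked what the inhibitor does alone and beside adenosine, and how the untreated sets compare, but in each the batch and the group cannot be told apart. R differed from DNT in 10814 of 14918 genes (5177 higher, 5637 lower in R), and RA from ADO in 10930 (4953 higher, 5977 lower in RA). DNT differed from WT, both untreated, in 9352 of 14877 (4587 higher, 4765 lower in DNT). Scaling to library size only shifted the median of all genes by −0.58 for R against DNT and by −0.50 for RA against ADO, and with it 112 and 3 called genes turned direction. The counts then were 2686 higher and 8328 lower for R against DNT, and 2873 and 8137 for RA against ADO, so the balance of these 2 comparisons depends on the scaling.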

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

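The tests of other-cell RNA, of induction and of a wrong label in the ATPgs set, of transcript length and depth for the spread among the inhibitor-only libraries, and of macrophage RNA and of set differences for the interferon genes were chosen only after the result was seen.

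The adenosine effect differed with and without the inhibitor, by a test of the difference itself, for 136 genes upward and 469 downward, and set and inhibitor cannot be told apart in it. The test gave each gene a single dispersion over sets of unequal spread, so its adjusted p-values may be too small. Among the named genes the differences were −5.36 for Ifit1bl1, −4.66 for Rsad2, −3.69 for Oasl1, −3.65 for Ifit3, −3.64 for Rtp4 and −3.22 for Ifi204, all induced by interferon, and −2.70 for Sh2d1b2. The receptor, ectoenzyme and early genes differed by −0.65 (Adora2a), −0.78 (Nt5e), 0.68 (Entpd1), −1.08 (Fos) and −1.23 (Igf1r). The others were 2.13 for Dnah17, 1.85 for Cyp1b1, 1.72 for Stra6, 1.69 for Slc7a2, 1.39 for Cxcl3, 1.22 for Ramp3, 1.21 for Ccl1, 1.19 for Slc1a2 and 1.11 for Il10. List medians of the difference were −1.56 for interferon response, −0.34 for cAMP-CREB, 0.031 for T cell cytokines, 0.12 for ATF4, 0.34 for endoplasmic reticulum stress, −0.39 for cholesterol synthesis, −0.55 for B cell and −0.70 for macrophage genes.

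The ATPgs effect differed from the adenosine effect for 1284 genes upward and 1440 downward. Each ligand was tested in a set of its own, and the untreated sets differed in 9352 genes, so ligand and set cannot be told apart in this difference. Differences upward were 2.14 for C5ar1, 2.13 for Hspa1a, 2.11 for A3galt2, 2.0 for Plagl1, 1.91 for Dusp8, 1.32 for Mgll, 1.20 for Fos, 1.02 for Il10, 0.72 for Entpd1, 0.30 for Crem and 0.25 for Adora2b. Downward they were −2.09 for Art2b, −2.07 for Slamf6, −1.92 for Sgip1, −1.89 for Igf1r, −1.82 for Slc25a32, −0.89 for Shank1, −0.38 for Adora2a, −0.27 for Fasl and −0.15 for Gzmb. List medians were 0.31 for cAMP-CREB, 0.43 for AP-1, −0.56 for interferon response, 0.23 for ATF4, 0.094 for endoplasmic reticulum stress, −0.23 for cell cycle, 0.10 for cholesterol synthesis, −0.29 for T cell identity and 0.86 for macrophage genes. Macrophage markers were higher only in WTATPgs replicates 1 and 2. Whether RNA of other cells took part in the macrophage median or in C5ar1 was not tested.

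Every split of the libraries was tested, and in each the side with more really treated libraries kept the name treated. For the difference with minus without inhibitor the real split of 100 gave 605 genes and the highest other 169, and for ATPgs minus adenosine they gave 2724 and 506. These splits say nothing about chance in the differences, because mixing treated with untreated libraries puts the treatment effects into the spread. The 81 splits that mixed both sets gave 0 genes each time, and those that mixed 1 set gave 32 to 169 and 42 to 506. For the comparisons of 3 with 3 libraries, the 10 splits are too few for a share under 0.05. The real values were 5612 for ATPgs, 7281 for adenosine, 147 for adenosine under the inhibitor, 10814 for R against DNT, 10930 for RA against ADO and 9352 for DNT against WT, with 0 in the highest other split each time, and 1 split, the real one, as large.

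Markers of myeloid cells and B cells were higher in WTATPgs replicates 1 and 2 than in WT and not in replicate 3. The myeloid list had a median of −0.14 in replicate 3, so its median was not raised in every ATPgs library. That value is part of the pattern itself and is no separate test of its cause. Induction of these genes by ATPgs therefore stays open, also for single genes such as Cd14. A wrongly labelled untreated library is argued against because genes changed at least 2-fold by adenosine moved by a median of 0.72 in the adenosine direction in replicate 3, against 0.67 and 0.70 in the others (555 genes). RNA of other cells in different amounts may explain the markers. The B cell list, with a median of −1.20 in replicate 3, moved with the myeloid one, but this too is part of the pattern. The labels name no sort or gate that would remove such cells. Among their abundant genes, Lyz2 went from 4.83 to 16.1 CPM (SD 0.272 and 9.57) and S100a8 from 6.38 to 23.0 CPM, while Cd74 (35.0 and 40.0 CPM) and Ctss (31.5 and 36.9 CPM) had a high baseline in WT.

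The 3 inhibitor-only libraries varied more than those of any other group, with a chi-square per gene of 48.8 to 235 between pairs, against at most 29.2 in the others. A trend over transcript length is argued against as the whole cause, since removing it left a coefficient of variation of 17.5% against 19.6%. Depth is argued against because the pair closest in total counts still differed with a chi-square per gene of 102. A single library standing apart is argued against as the whole cause, since the coefficient stayed at 11.7% or more without any 1 of them. It was 11.7% without R replicate 3, 14.9% without 2 and 21% without 1, against 10.6% and 2.74% in the other sets. The 10.6% of set 1 included WTATPgs replicate 3, which stood apart. R replicate 3 did add to the spread. Its pairs had a chi-square per gene of 102 and 235, against 48.8 for the pair without it. The R libraries also differed in RNA composition. Ribosomal protein RNA held 13.3%, 10.9% and 16.9% of counts in R replicates 1 to 3, against 12.4% to 13.1% in RA. Mitochondrially encoded RNA held 3.66%, 3.14% and 5.47%, against 3.71% to 3.95% in RA. Whether RNA quality took part in the spread was not tested. No biological explanation was tested either, so the source stays open.

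Of 36 interferon response genes 31 rose and 1 fell with adenosine, and of 32 under the inhibitor 0 rose and 13 fell. The list under the inhibitor did not pass with an estimated correlation (adjusted p = 0.106, over the alternatives 5.34e-22 to 0.106). Scaling between libraries is argued against because the list median under the inhibitor stayed at −0.48 or lower under the other scalings, and the length trend because it was −0.61 with the transcript length offset. Macrophage RNA cannot be told apart from a change in the T cells, since the 9 macrophage genes had a median of −0.024 with a median absolute deviation of 0.58, against −0.60 and 0.91 for the 32 interferon genes. Natural killer and dendritic lists, with medians of −0.17 and −0.35, had adjusted p = 0.0406 each in the same comparison, and adjusted p = 0.639 and 0.305 with an estimated correlation, and RNA of those cells stays open as well. A difference between the sets other than the inhibitor cannot be told apart either, because the design confounds them: the untreated sets differed by a median of 0.39 on this list (DNT minus WT), R and DNT by −0.88, and RA and ADO by −2.83.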

How the results depend on the processing

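The transcript length offset and the weights per set were chosen after seeing the data; all other tests here were planned. No gene called in both settings turned direction in the 5 treatment and difference comparisons.

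Against a log2 fold change of 0.5, 425 genes were higher and 234 lower with ATPgs, 513 and 263 with adenosine, 17 and 49 with adenosine under the inhibitor, 18 and 115 for the difference with minus without inhibitor, and 63 and 38 for ATPgs minus adenosine, as a stricter test allows fewer calls. With all 18 libraries in a single fit 1498 were lower with ATPgs, 1439 and 870 were higher and lower with adenosine, 885 and 893 under the inhibitor. It gave 391 higher in the inhibitor difference, 157 and 145 in the ligand difference, and 5217 differed between the untreated sets. A single dispersion over sets with different spread is built into this fit, and likewise into the main fits of 12 libraries for the differences. DESeq2 gave 155 and 308 under the inhibitor and 519 and 781 for its difference. No filter gave 156 and 329 under the inhibitor, library size only 48 lower there and 72 and 168 for the difference, and the length offset 79 and 196 under the inhibitor. The cause of these was not tested.

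Leaving out 1 library at a time gave ranges of 1778 to 4186 higher and 2080 to 4195 lower for ATPgs, 3389 to 3526 and 3292 to 3379 for adenosine, 5 to 725 and 31 to 994 under the inhibitor, 45 to 1633 and 230 to 1417 for its difference, and 913 to 2309 and 1030 to 3058 for the ligand difference. The highest of these came without WTATPgs replicate 3 or R replicate 3, except for adenosine, where they came without ADO replicate 1.

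Shared calls at 2-fold or more were 155 higher and 68 lower for ATPgs and adenosine, 16 and 20 for adenosine without and with inhibitor, and 16 and 10 for ATPgs and adenosine under the inhibitor. DESeq2 gave 109 and 138, and 81 and 99, for the last pairs. The chemokine list with adenosine reversed under fry (adjusted p = 0.0266, over the alternatives 0.0266 to 0.677). A value that passed in neither the main fit nor the alternative counted as on the same side, whatever its sign. Over all alternatives and named genes, values on the same side of the threshold numbered 1294 for ATPgs, 1253 for adenosine, 1135 under the inhibitor, 765 for its difference and 803 for the ligand difference. Those that lost the call numbered 56, 22, 68, 37 and 54, and those that gained it 13, 0, 129, 12 and 23. For list tests the values on the same side numbered 173, 187, 179, 290 and 282, and those that lost the call 14, 4, 12, 15 and 13, and those that gained it 11, 6, 7, 1 and 11.

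Replicate numbers showed no clear pairing of the libraries. Residuals of same-numbered control and treated libraries correlated across genes, which are not independent replicates, at −0.02, 0.00 and −0.02, 0.01, 0.02 and −0.00, and 0.05, −0.20 and −0.13. With 3 libraries per group these values cannot exclude a shared culture or preparation. A block for replicate number gave 19 and 141 genes for the inhibitor difference.

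On simulated data edgeR recovered 7.76% of changes of 1.5-fold under the inhibitor, where the spread between libraries was widest, against 52.8% with ATPgs and 69.9% with adenosine. The simulated libraries shared each gene's dispersion, so the unequal spread of R and RA is not part of these rates.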

Other observations

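All results in this part come from tests planned before the data were examined. The gene lists below are not among the 18 described for each treatment. With ATPgs, of 28 purine and pyrimidine synthesis genes 3 rose and 16 fell (3 and 19 adjusted over the list alone), the falls including Pfas (−0.69), Gart (−0.51), Cad (−0.45) and Shmt2 (−0.31). That list had adjusted p = 0.00211, and adjusted p = 0.753 with an estimated correlation. Of 23 hypoxia response genes 7 rose and 0 fell (7 and 0 adjusted over the list alone), among them Hilpda (1.07), Vegfa (0.84), Mxi1 (1.33) and Pfkfb4 (1.48). Their list had adjusted p = 0.00937, and adjusted p = 0.753 with an estimated correlation. Of 18 heat shock genes 4 rose and 10 fell (4 and 10 adjusted over the list alone), Dnajb4 (1.06), Hspa1a (2.42) and Hspa1b (1.79) upward and Hsp90ab1 (−0.30) downward. Of 29 lineage factor genes 9 rose and 8 fell (10 and 8 adjusted over the list alone), Ikzf2 (1.05), Foxo1 (0.85) and Stat3 (1.02) upward and Stat5a (−0.93) downward. Rises and falls were 12 and 8 of 30 NF-kB targets (13 and 8 adjusted over the list alone), 12 and 6 of 26 p53 targets (12 and 6), 3 and 3 of 22 glycolysis genes (3 and 3), 1 and 5 of 35 oxidative phosphorylation genes (1 and 2). Among markers of other cells they were 4 and 3 of 16 for dendritic cells (4 and 3 adjusted over the list alone), 6 and 2 of 16 natural killer markers (7 and 2), 0 and 0 of 8 gamma delta T cell markers (0 and 0), 0 and 1 of 9 erythroid and platelet markers (0 and 1) and 3 and 0 of 7 stromal and endothelial markers (4 and 0).

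With adenosine, of 29 lineage factor genes 11 rose and 14 fell (11 and 14 adjusted over the list alone), Stat3 (0.98) and Ikzf2 (0.83) upward and Irf4 (−0.93) and Stat5a (−0.50) downward. Of 23 glycolysis genes 10 rose and 8 fell (10 and 8), Slc16a3 (0.77) and Tpi1 (0.34) upward and Hk2 (−0.68) and Slc2a3 (−0.41) downward. Rises and falls were 10 and 8 of 30 NF-kB targets (10 and 8 adjusted over the list alone), 11 and 8 of 26 p53 targets (11 and 8), 4 and 9 of 18 heat shock genes (4 and 9), 10 and 4 of 35 oxidative phosphorylation genes (10 and 4), 5 and 13 of 28 purine and pyrimidine synthesis genes (6 and 14) and 8 and 6 of 23 hypoxia genes (8 and 6). They were 7 and 4 of 16 dendritic cell markers (7 and 4 adjusted over the list alone), 9 and 4 of 14 natural killer markers (9 and 4), 0 and 2 of 7 gamma delta markers (0 and 1), 1 and 2 of 5 erythroid and platelet markers (1 and 2), and 3 and 1 of 6 stromal markers (3 and 1). None of these lists passed the threshold with adenosine.

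Under the inhibitor 3 of 16 natural killer markers fell with adenosine (4 adjusted over the list alone), Ncr1 (−2.93), Fcgr3 (−1.61) and Tyrobp (−1.63), while Klri2 (1.22) did not pass. The natural killer list had adjusted p = 0.0406, and adjusted p = 0.639 with an estimated correlation. Of 30 NF-kB targets only Ccr7 rose (0.88), of 29 lineage factor genes only Rora rose (1.03), and of 3 stromal markers Madcam1 (−1.99) and Vwf (−1.42) fell. None passed of 26 p53 targets, 18 heat shock, 22 glycolysis, 34 oxidative phosphorylation, 27 purine and pyrimidine synthesis, 22 hypoxia, 15 dendritic, 6 gamma delta and 3 erythroid and platelet genes. The glycolysis list had adjusted p = 0.0125, and adjusted p = 0.639 with an estimated correlation. The dendritic list had adjusted p = 0.0406, and adjusted p = 0.305 with an estimated correlation.

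In the ligand difference, of 28 purine and pyrimidine synthesis genes 1 was higher and 10 lower with ATPgs than with adenosine (2 and 12 adjusted over the list alone), with adjusted p = 0.00102, and adjusted p = 0.531 with an estimated correlation. Of 23 hypoxia response genes 5 were higher (5 adjusted over the list alone), with adjusted p = 0.00118, and adjusted p = 0.531 with an estimated correlation. Of 35 oxidative phosphorylation genes 0 were higher and 4 lower (0 and 4 adjusted over the list alone), with adjusted p = 0.0102, and adjusted p = 0.545 with an estimated correlation. In the difference with minus without inhibitor, 0 of 23 glycolysis genes were higher and 3 lower (0 and 4 adjusted over the list alone), with adjusted p = 0.00929, and adjusted p = 0.513 with an estimated correlation.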
